A study of Danio rerio with 8 samples.

How the data were processed

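RNA was measured in whole zebrafish embryos with 1-colour oligonucleotide arrays, on which each probe is a spot whose brightness rises with the amount of its labelled transcript. Per the labels' protocols, dechorionated embryos were kept at nominal concentrations of 0 or 7.37 µM triclosan (TCS) with 0.64% dimethyl sulfoxide (DMSO) between 6 and 48 hours post fertilisation (hpf), total RNA was extracted from homogenised embryos after a DNase step, and Cy3-labelled cRNA was made with a whole-transcript amplification kit. Each array held the RNA of a pool of 8 embryos. Samples were assigned to DMSO or TCS, with 4 arrays each, from their own labels, which also gave the replicate numbers. The arrays are named here by group and replicate number, such as TCS 2.

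The deposited scanner tables hold spot intensity on a linear scale, made with Agilent Feature Extraction 11.5.1.1 and its protocol GE1_1105_Oct12 from scans of the custom design 069507, per the file headers. The submitters' processing notes name Agilent Feature Extraction 11 and limma without saying how they were applied. In these tables the processed intensity is the spot mean after background subtraction and detrending, with substitute values for very dim spots, per the file headers, and no scaling between arrays had been done. A deposited table of log2 values for the same arrays came from the authors with unstated steps. Each of its columns followed the deviations of its own array best across probes (Spearman's rho from 0.912 to 0.963, against at most 0.312 with any other array), and its column medians lay between 8.40 and 8.41, so it was used as an alternative. Its scale is log2 and its direction is that of the intensities, while its background correction and any averaging of probes stay unknown.

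The arrays carried 62976 spots, of which 1319 were controls and 61657 were spots of 60022 distinct probes of 44 to 58 bases. Gene symbols of the array design named 38283 probes and 21131 different genes. The other 21739 probes carried a transcript accession or a gene prediction, and 12252 of these gave an Ensembl gene, of which 8148 were in the gene name table used here (assembly GRCz12tu). Symbols are printed as the array gives them, and current symbols from that table follow where they differ. Coordinates are those the array files give for each probe's transcript in build Zv9, as chromosome, first and last base. No genome sequence or annotation of that build was used here, so exons and untranslated regions are not stated.

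For the main setting, control spots and spots marked as non-uniform or as population outliers were left out (17 to 79 spots per array), log2 of the processed intensity was taken, and each array's 75th percentile over non-control probes was subtracted. A value of 0 is thus an array's 75th percentile. Spots of a probe were averaged. A probe was tested if it was well above background on at least 4 of the 8 arrays, and where several tested probes carried a symbol, the probe with the highest mean over all 8 arrays stood for the gene. A probe without a symbol was a feature of its own. Of the 40954 features tested, 20589 were genes with a symbol and 20365 carried an accession alone, and 81 lacked a value on some array. Differences are TCS minus DMSO on the log2 scale. They were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) with Benjamini-Hochberg adjustment over all features tested and a threshold of 0.05. Where a probe was not well above background on any array of a group, the change is given as at least N-fold, from the bright group's mean against the dim group's mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background.

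Gene lists for tissues, pathways and stress responses, 46 in all, were fixed before the data were examined, as were the design, the naming rule and most alternatives. They held 1388 entries, of which 1149 were matched by symbol and 119 through another symbol in the name table, while 99 were not tested or not matched and 21 repeated a feature already in the same list. Lists with at least 5 tested members were tested with limma's camera (two-sided, preset correlation of 0.01, Benjamini-Hochberg over the lists), beside camera with an estimated correlation and fry. Fry asks whether the genes of a list move on balance one way, without comparing them with other genes. The named genes follow a rule. First came the 12 symbols with the largest positive and the 12 with the largest negative differences among those past the threshold with all 4 TCS arrays on the same side of all 4 DMSO arrays, leaving out clone-style names. To these were added up to 4 members with the smallest p of each list that passed camera, cyp1a, fabp10a and tfa, and up to 2 members past the threshold from each other list. This gave 137 genes. A gene outside the rule is named only with a remark that it was chosen after its values were seen.

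Precision rests on the number of arrays, 4 per group. On simulated arrays with the measured spread (40873 features, 4 against 4), the same limma steps recovered 18% of 2-fold and 71% of 4-fold changes. They called 2 unchanged features, and called the list whose members were shifted by -0.5 with 0 others. The simulated noise was independent between features and held no slide effect, whereas estimated correlations in the measured lists reached 0.46. The simulation therefore cannot show how often lists of correlated genes are called by mistake. Slides and scan days were read from the files and numbered. Slide 1 held DMSO 3, DMSO 4 and TCS 4, slide 4 held DMSO 1 and TCS 3, and the other 3 slides held 1 array each. Scan day 1 held DMSO 2, scan day 2 DMSO 3, DMSO 4, TCS 1 and TCS 4, and scan day 3 DMSO 1, TCS 2 and TCS 3. Arrays lay in row 1 (5 arrays) or row 2 (DMSO 4, TCS 3 and TCS 4) of their slide. Together, 2 slides, 2 scan days and both rows held both groups, which makes 6 batches in which a difference can be read. These batches regroup the same arrays, so they overlap and are not independent of each other. As a fixed block, a slide or scan day that holds 1 array takes that array out of the group comparison. Slide as a fixed block therefore compares the groups on slides 1 and 4 alone, and scan day as a block does so without DMSO 2. Calls lost with these blocks can come from the loss of arrays as well as from slide or scan day.

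Alternatives tried were quantile normalization, the array median in place of the 75th percentile, normexp on mean and local background intensity (offset 50) with either scaling, the authors' log2 values, other filters on dim probes, other rules for several probes, outlier spots kept, eBayes with trend and robust settings, array weights, slide as a fixed or random block, replicate number as a block, a fold-change minimum of 1.5, an adjusted p under 0.01, and each array left out. After the data had been seen, scan day and slide row were added as blocks, and like sequences (blastn 2.17.0, 85% identity over 35 bases) were counted once. Gene symbols were then also counted alone, with p still adjusted over all features, and TCS 2 and DMSO 2 were left out together. Statmod 1.5.0 served the random block, and tables and plots were made with Python 3.11.15, pandas 2.3.3, networkx 3.6.1 and matplotlib 3.10.9. Permutation p-values of single values are exact and two-sided.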

Results

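The series measured transcripts of whole zebrafish embryos at 48 hpf with 1-colour microarrays, after exposure to TCS (triclosan, an antimicrobial agent of consumer products) or to the solvent DMSO alone. Exposure began at 6 hpf, with TCS at 0 or 7.37 µM and 0.64% DMSO, and every sample pooled 8 embryos. There were 4 DMSO and 4 TCS arrays, described in the labels as biological replicates. The labels name no clutches, so the p-values rest on the spread between these pools, and the number of arrays limits their precision. The 75th percentile of processed signal was 545, 728, 726 and 767 on DMSO 1 to DMSO 4 and 755, 315, 683 and 581 on TCS 1 to TCS 4. Between 90.3% and 95.9% of spots were well above background and 0 spots were saturated. Across features, which are not independent replicates, log2 values correlated at r of 0.940 to 0.956 among DMSO arrays and 0.952 to 0.969 among TCS arrays. Between the groups r was 0.918 to 0.968. On the first principal component DMSO 2, DMSO 3 and DMSO 4 lay between -102.9 and -32.6, and TCS 2, TCS 3 and TCS 4 between 46.8 and 79.3. The scores of DMSO 1 (7.34) and TCS 1 (-3.71) lay between these.

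**Figure D1:**
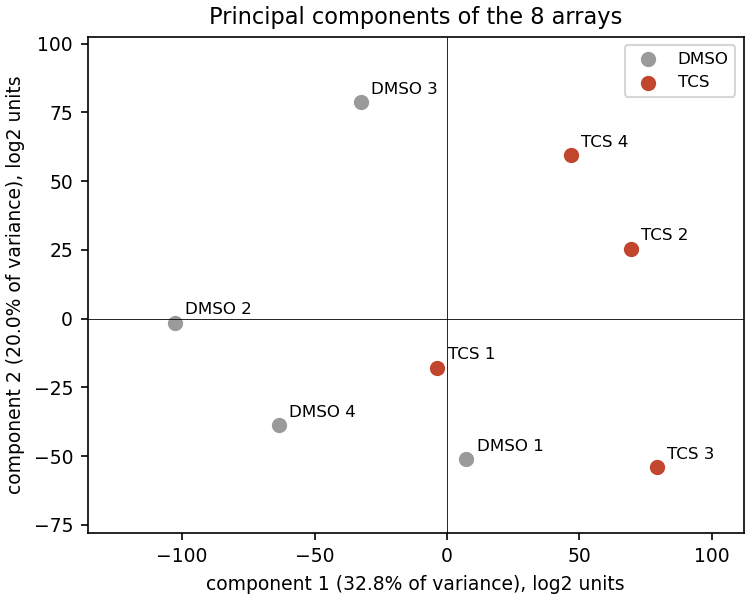
Each point is 1 of the 8 arrays, placed by its scores on principal components 1 (32.8% of variance, horizontal) and 2 (20.0%, vertical) of the log2 values, with DMSO in grey and TCS in red. DMSO 1 and TCS 1 sit close to 0 on component 1 while the other 3 arrays of each group lie apart.

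The comparison asks which transcripts differ at 48 hpf after TCS exposure, and the title of the series names toxicity to the liver. Transcripts of hepatocyte markers and plasma proteins were far lower in exposed embryos. The embryos were measured whole, so the tissue in which these transcripts fell is not known. Transferrin-a (tfa), the iron carrier of plasma, fell by 4.53 ± 0.62 on the log2 scale (SE, n = 4 arrays per group), or 23.1-fold (limma adjusted p = 0.0107; 35.6-fold without TCS 1). The liver fatty acid binding protein fabp10a, a hepatocyte marker, fell by 2.63 ± 0.37, or 6.21-fold (limma adjusted p = 0.0115, or 0.0564 with scan day as a block). Of 28 measured genes for hepatocyte markers and plasma proteins 19 fell, as did 16 of 37 photoreceptor and retina genes and 16 of 42 genes of neurons and glia. Fewer genes rose, among them atf3, a transcription factor induced by stress, by 2.02 ± 0.16, and isg15, a ubiquitin-like protein induced by interferon, by 2.92 ± 0.45 (limma adjusted p = 0.00103 and 0.0154). Another probe of atf3 differed by +0.73.

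Of 40954 features tested with limma, 317 were higher and 1121 lower in TCS than in DMSO at an adjusted p under 0.05, so that 78.0% of the 1438 changed features were lower. Among genes with a symbol 93 rose and 815 fell. At least 2-fold changes were seen in 209 of the higher and 818 of the lower features, and the median difference of all features was +0.10. All 4 TCS arrays lay on one side of all 4 DMSO arrays for 12.6% of features, against 2.86% by chance. The counts depended on which array was left out. They were 42 higher and 217 lower without DMSO 2, 52 and 344 without DMSO 3, and 34 and 241 without DMSO 4. Without TCS 2 they were 45 and 277, without TCS 3 52 and 318, and without TCS 4 60 and 362. They moved less without DMSO 1 (294 and 1051) and without TCS 1 (250 and 1242). With scan day as a block limma called 63 features higher and 260 lower, and with slide row as a block 142 and 508. Scan day 1 held DMSO 2 alone, so the scan day block takes DMSO 2 out of the comparison. Calls lost with it, here and below, can come from the loss of that array as well as from scan day. With slide as a fixed block limma called 0 either way (5602 at an unadjusted p under 0.05), whereas slide as a random block gave 615 and 1691. The fixed block compares the groups on slides 1 and 4 alone, so its 0 calls cannot tell an effect of slide from the loss of arrays. In the 6 batches that held both groups, the median of the higher features was 1.06 to 1.22 and that of the lower features -1.34 to -1.09. Their signs there carry no further information, because the groups did not overlap for 1436 of the 1438 features.

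**Figure D2:**
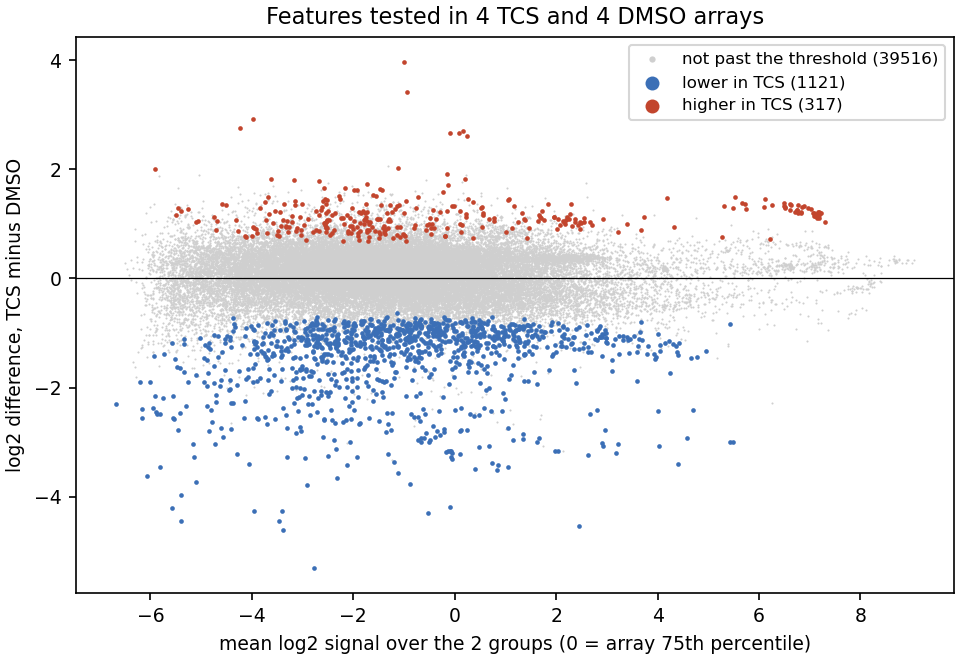
Each point is 1 of the 40954 features tested, with its mean log2 signal over both groups on the horizontal axis (0 is the array 75th percentile) and its log2 difference, TCS minus DMSO, on the vertical axis. Red points are the 317 features higher in TCS and blue points the 1121 lower, at a limma adjusted p under 0.05, and the decreases reach larger sizes than the increases.

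Among genes under the naming rule, which leaves out clone-style names, those with the largest increases had diverse roles. After isg15 (chromosome 5, 21895629 to 21896102, build Zv9), which was well above background on 3 of the 4 DMSO arrays, and atf3 (chromosome 20, 37819241 to 37825345) came irf7, a transcription factor of the interferon response, higher by 1.83 ± 0.17 (limma adjusted p = 0.00201). Nfe2l2b, a paralogue of the oxidative stress regulator Nrf2, rose by 1.81 ± 0.25, and igfbp1a, which binds insulin-like growth factors, by 1.70 ± 0.26 (limma adjusted p = 0.0107 and 0.0142). Cyp1b1 (chromosome 13, 42664264 to 42671929), a cytochrome P450 and target of the aryl hydrocarbon receptor, rose by 1.53 ± 0.17, or 2.89-fold (adjusted p = 0.00509 in limma). The related cyp1a (chromosome 18, 4974676 to 4985566), a common marker of that receptor, differed by +0.68 (SE 0.22) and did not pass (limma adjusted p = 0.143). Smaller increases were found for the phosphatase gene inpp4ab (+1.52), the actin regulator wasa (+1.5005) and the Polycomb gene cbx7a (+1.498). The phosphatase subunit ppp2r5eb (+1.46), the matrix protease mmp9 (+1.44) and crebrf (+1.41) were also higher, and limma adjusted p of these 6 genes ran from 0.0143 to 0.0469. Other probes of inpp4ab and ppp2r5eb gave differences down to +0.39 and -0.13. With scan day as a block isg15 differed by +3.03, atf3 by +1.96, irf7 by +1.89 and cyp1b1 by +1.53. Within the 6 batches, the difference of isg15 was +2.52 to +3.82 and that of atf3 +1.72 to +2.11. On TCS 2 the log2 value of isg15 was -4.005, against -2.09 to -1.95 on the other TCS arrays. The calls of inpp4ab, wasa, cbx7a, ppp2r5eb and mmp9 were lost with scan day as a block (adjusted p = 0.0612 to 0.086). Cbx7a and mmp9 each passed in 1 of the 8 fits that left out an array, and wasa in 0.

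The largest decreases under the same rule included genes of the eye, the liver and secreted proteins. Gnb3a (chromosome 16, 13772550 to 13799769), a G protein subunit of cone photoreceptors, fell by 5.30 ± 0.36 (limma adjusted p = 0.000551). It was well above background on 2 of the 4 TCS arrays, so the size of its difference is uncertain. Genes of complement component C3 near each other on chromosome 1 fell, with limma adjusted p from 0.0216 to 0.0383. They were c3b (now c3a.2, 56776445 to 56813502, -4.62 ± 0.97), c3c (now c3a.3, 56821384 to 56867340, -3.57 ± 0.64) and c3a (now c3a.1, 56676993 to 56723747, -3.46 ± 0.60). All 5 probes of tfa (chromosome 2, 16581385 to 16592930) gave differences between -4.53 and -3.63. The sulfotransferase gene sult3st3 and the guanylate kinase gene guk1b were not well above background on any TCS array. They were at least 5.78-fold and at least 4.91-fold lower (limma adjusted p = 0.000551 and 0.00101). Decreases were also large for ependymin, epd (-4.26), the cellular retinol binding proteins rbp2b (-4.18) and rbp2a (-3.77), angiotensinogen, agt (-3.79), and urate oxidase, uox (-3.65). Their limma adjusted p ran from 0.000551 to 0.0118. Among the TCS arrays epd was well above background on 1, c3b on 2, and agt and uox on 3 each, so their sizes are uncertain as well. With scan day as a block gnb3a differed by -5.26, tfa by -4.24 and fabp10a by -2.53, and within the 6 batches these genes differed by -5.73 to -4.95, -5.80 to -3.57 and -3.03 to -2.20. The difference of c3b within batches was -6.56 to -2.66, and 1 of the 8 fits that left out an array called it (highest adjusted p = 0.118, without TCS 2). With scan day as a block the calls of fabp10a and rbp2b (adjusted p = 0.0564 each), c3a (0.061), c3c (0.0756) and c3b (0.098) were lost. Without TCS 1 the difference of tfa was -5.15, that of c3b -5.66 and that of c3c -4.16, and without TCS 3 those of c3b and c3c were -3.97 and -2.96.

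**Figure D3:**
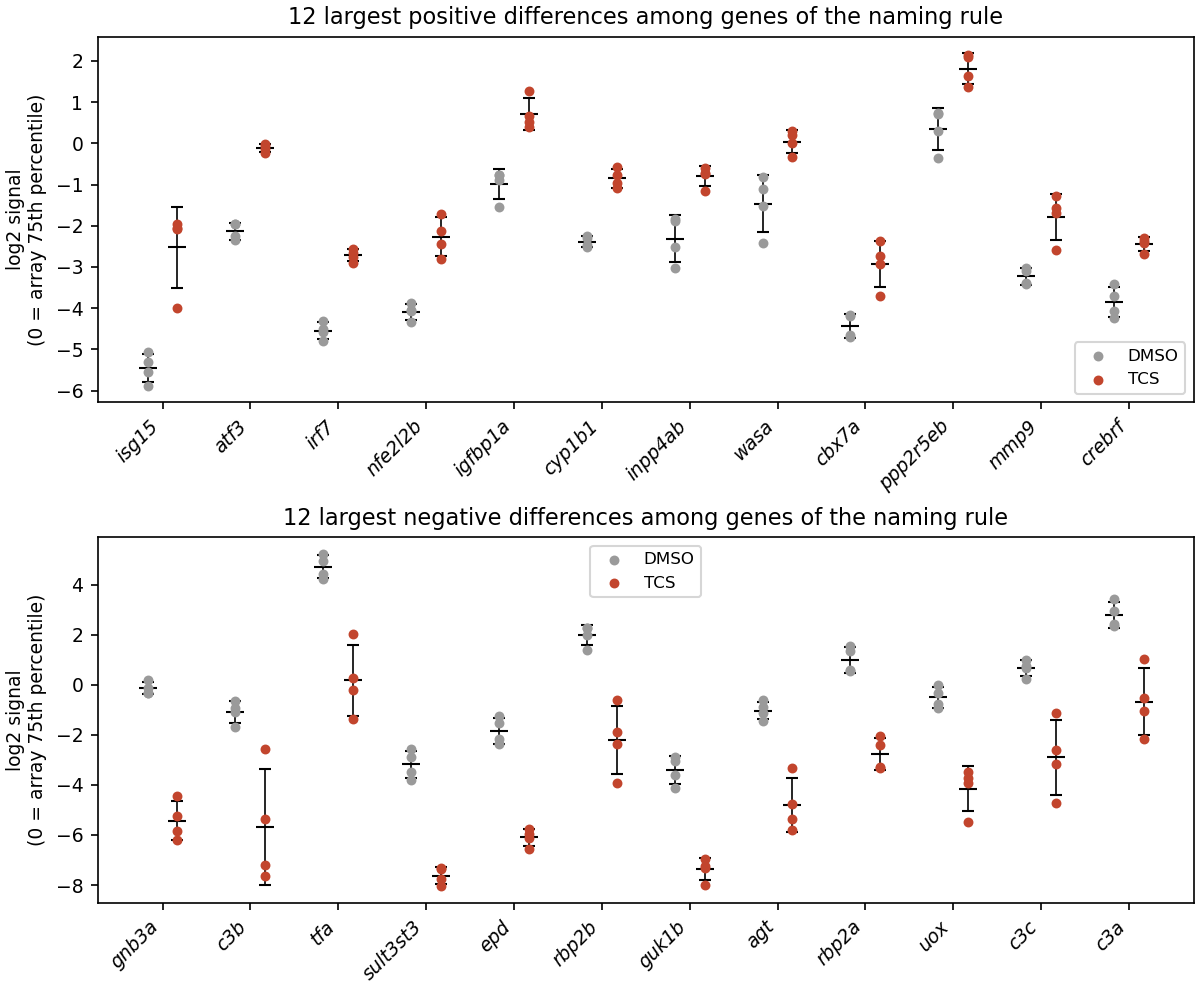
Points are the log2 signals of single arrays (0 is the array 75th percentile) for the 12 genes with the largest positive differences under the naming rule, which leaves out clone-style names (upper panel), and the 12 with the largest negative ones (lower panel), DMSO in grey and TCS in red, with the mean and SD of 4 arrays. The groups do not overlap for any of these genes, which the naming rule required, and isg15 on TCS 2 lies at -4.005.

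Of the 137 named genes 102 passed the threshold. The groups did not overlap for any of the 102, so their sign within a batch could not have differed. The call held in every fit that left out an array for 37 of them. By array, 82 passed without DMSO 1, 40 without DMSO 2, 50 without DMSO 3, 39 without DMSO 4, 92 without TCS 1, 45 without TCS 2, 51 without TCS 3 and 54 without TCS 4. With scan day as a block 42 passed, fabp10a not among them, and with slide row as a block 66. With slide as a fixed block, which compares the groups on slides 1 and 4 alone, 0 passed, and the lowest limma adjusted p was 0.201. The genes atf3, epd, fkbp5, gnb3a, opn1lw2, rbp2a, rcv1, rlbp1a and try kept the call under every alternative in which they were tested, other than the slide block. Gnb3a and epd were not tested where all 8 arrays had to be well above background. Of the 46 gene lists fixed beforehand, camera with a preset correlation placed 1 higher and 24 lower in TCS, relative to other features. The lists hold gene symbols, whose median difference was -0.03, while the other features include those without a symbol, with a median of 0.22. This tilts the comparison towards lower calls, most of all for lists with small shifts. No list was tested against gene symbols alone. With an estimated correlation camera placed 0, with adjusted p from 0.079 to 0.577 for these 25 lists. The direction of the mean held for the median in all 6 batches for 22 of the 25. The batches share arrays, so these are not 6 separate checks.

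**Figure D4:**
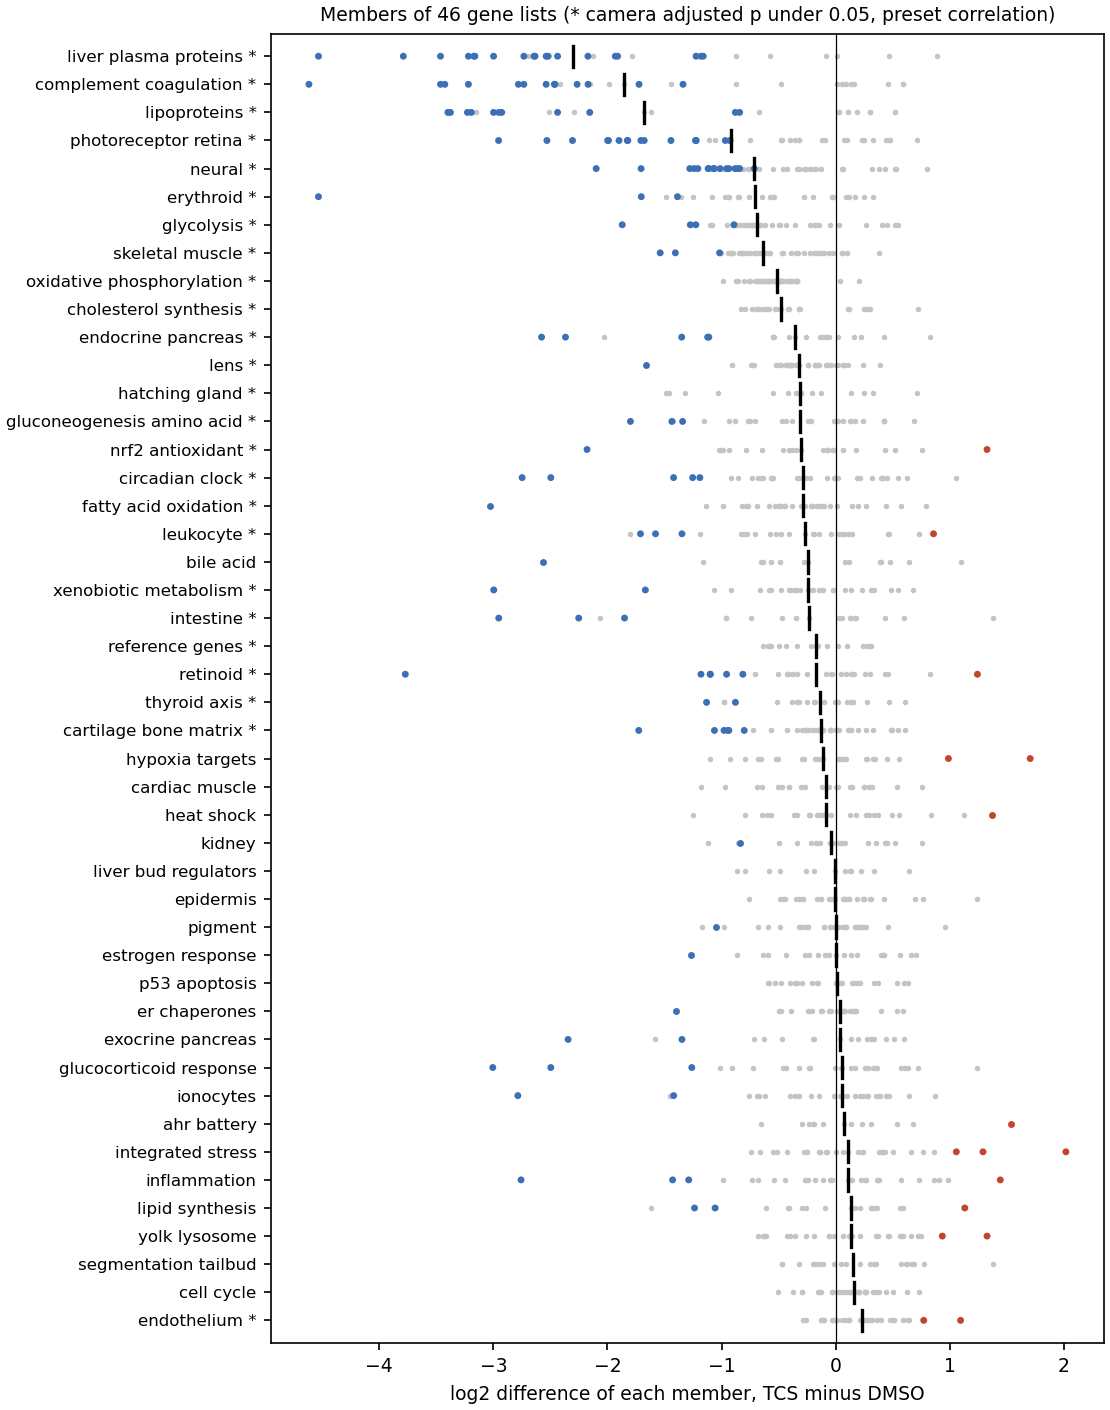
Each point is a member of 1 of the 46 lists, placed by its log2 difference, TCS minus DMSO, in blue or red where it passed the limma threshold over all features and in grey where it did not, and the black bars are list medians. Asterisks mark the 25 lists with a camera adjusted p under 0.05 at the preset correlation, and the liver plasma protein, complement and lipoprotein lists have the lowest medians.

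The lists of hepatocyte markers and plasma proteins, of complement and coagulation factors and of lipoproteins had the lowest medians. The first shares entries with the others, such as fga, fgb and fgg with the complement list and apoa2 with the lipoprotein list. Their results are therefore not independent of each other. RNA came from whole embryos, so the tissue in which these transcripts fell was not measured. In the list of hepatocyte markers and plasma proteins 19 of 28 genes fell (22 lower and 1 higher when adjusted over the list alone), with a median of -2.30. Its camera adjusted p was 1.44e-17 (adjusted p = 0.202 with an estimated correlation). Examples are tfa, agt, the inter-alpha-trypsin inhibitor gene zgc:110377 (now itih3a.1, -2.64) and fabp10a (chromosome 16, 56117757 to 56122739). Fabp10a was lowest on TCS 2, at -4.77 against -3.14 to -3.09 on the other TCS arrays. TCS 1 had the highest TCS values of tfa (2.05 against -1.35 to 0.28), apoba (0.68 against -2.50 to -0.79) and c3b (-2.56 against -7.64 to -5.37), and the differences of tfa and c3b without it were -5.15 and -5.66. The list of complement and coagulation factors had a median of -1.85, with 13 of 29 lower (21 lower and 2 higher when adjusted over the list alone). Its camera adjusted p was 7.05e-12 (adjusted p = 0.202 with an estimated correlation). Leading members were the coagulation factors f7 (-3.43) and f10 (-2.17), complement component c8b (-2.46) and the complement regulator cfh (-2.78), with limma adjusted p from 0.00755 to 0.0165. Genes of lipoproteins and lipid transport had a median of -1.68, with 11 of 25 lower (17 lower and 0 higher when adjusted over the list alone). Camera gave an adjusted p of 1.19e-08 (adjusted p = 0.202 with an estimated correlation). Among them the apolipoprotein genes apoba (-3.38), apoea (-3.23), apoa2 (-3.00) and si:dkey-52k20.7 (now apoda.2, -2.16) fell. Without TCS 3 the difference of apoea was -2.61. Within the 6 batches the medians were -3.29 to -1.51 for plasma proteins, -2.74 to -1.13 for complement and -2.63 to -1.02 for lipoproteins. Their means of -2.01, -1.59 and -1.53 became -1.88, -1.45 and -1.44 with scan day as a block. With slide as a block they became -2.16, -1.70 and -1.84. Regulators and early markers of the liver bud had a median of -0.01 over 13 genes and 0 passed in limma over all features (1 higher and 3 lower at an unadjusted p under 0.05; 1 lower and 1 higher when adjusted over the list alone). Camera did not call this list (adjusted p = 0.411, or adjusted p = 0.538 with an estimated correlation). The calls of zgc:110377, apoba, c8b, cfh, apoea and apoa2 were lost with scan day as a block (adjusted p = 0.0509 to 0.0925). Apoa2 passed in 1 of the 8 fits that left out an array.

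Lists of the retina, the nervous system and the lens had medians below 0, and most of their members did not pass over all features. Of the photoreceptor and retina list 16 of 37 genes fell (19 lower and 1 higher when adjusted over the list alone), with a median of -0.92. The camera adjusted p was 4.96e-12 (adjusted p = 0.079 with an estimated correlation), the lowest of the 46 lists with an estimated correlation. The red cone opsin opn1lw2 (chromosome 11, 26414605 to 26416765) fell by 2.53 ± 0.24, or 5.78-fold. The recoverin gene rcv1 (now rcvrn2, -2.31), rlbp1a, which carries retinaldehyde (-1.90), and crx, a transcription factor of photoreceptors (-1.68), also fell. Limma adjusted p of these 4 genes ran from 0.000962 to 0.00353. In the list of neurons and glia 16 of 42 genes fell (24 lower and 1 higher when adjusted over the list alone), with a median of -0.72 and a camera adjusted p of 2.92e-13 (adjusted p = 0.202 with an estimated correlation). The synaptic genes snap25b (-2.099) and sypb (-1.28), the neuronal transcription factor neurod (now neurod1, -1.11) and the growth cone gene gap43 (-1.01) were among them. Lens genes had a median of -0.32, with 1 of 37 lower (4 lower and 0 higher when adjusted over the list alone), and a camera adjusted p of 8.53e-06 (adjusted p = 0.202 with an estimated correlation). The lens gene that fell was zgc:136220 (now crybgx, -1.66). Crygmx (-0.91), bfsp2 (-0.71) and lgsn (-0.74) had limma adjusted p from 0.0522 to 0.0692. Medians within the batches were -1.12 to -0.59 for the retina, -0.83 to -0.55 for neurons and glia and -0.45 to -0.20 for the lens. The means of -0.84, -0.57 and -0.30 became -0.83, -0.55 and -0.34 with scan day as a block and -0.77, -0.56 and -0.35 with slide as a block. The calls of sypb, neurod, gap43 and zgc:136220 were lost with scan day as a block (adjusted p = 0.0536 to 0.0686).

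Muscle and energy metabolism lists shifted by many small differences. Values were below 0 for 41 of 45 skeletal muscle genes, with a median of -0.64 and a camera adjusted p of 2.6e-13 (adjusted p = 0.202 with an estimated correlation). The fast troponin gene tnni2b.1 (-1.54), the myosin binding protein gene mybpc1 (-1.40) and the Z-disc gene ldb3b (-1.02) were the 3 that fell over all features (26 lower and 0 higher when adjusted over the list alone). Other probes of these genes gave differences up to -0.60, -0.56 and, with the opposite sign, +0.36. Myoz1b (-1.01) did not pass (limma adjusted p = 0.0533). Nuclear genes of the respiratory chain were below 0 in 48 of 50 cases, with a median of -0.52 and a camera adjusted p of 3.06e-16 (adjusted p = 0.202 with an estimated correlation). In limma 0 of them passed over all features (34 lower and 0 higher at an unadjusted p under 0.05; 29 lower and 0 higher when adjusted over the list alone). Atp5g1 (now atp5mc1, -0.76), cox4i2 (-0.87), ndufa8 (-0.63) and cycsb (-0.70) had adjusted p from 0.0522 to 0.106. Of 38 genes of glycolysis and glucose transport 4 fell (21 lower and 1 higher when adjusted over the list alone), with a median of -0.69 and a camera adjusted p of 1.37e-09 (adjusted p = 0.202 with an estimated correlation). They were pgam1b (-1.27), the liver and islet glucose transporter slc2a2 (-1.87, of uncertain size, as it was well above background on 3 of the 4 TCS arrays), pfkma (-1.23) and pgam1a (-0.89), of which pgam1a had another probe at +0.08. Medians within batches were -0.81 to -0.43 for muscle, -0.72 to -0.41 for the respiratory chain and -0.84 to -0.51 for glycolysis. The means of -0.56, -0.53 and -0.55 became -0.55, -0.44 and -0.49 with scan day as a block and -0.74, -0.51 and -0.58 with slide as a block. The calls of mybpc1, ldb3b, slc2a2, pfkma and pgam1a were lost with scan day as a block (adjusted p = 0.0503 to 0.109). Slc2a2 and pgam1a each passed in 1 of the 8 fits that left out an array.

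Blood, islet and gut genes also had medians below 0. Of 26 red blood cell genes 3 fell (12 lower and 0 higher when adjusted over the list alone), with a median of -0.70 and a camera adjusted p of 1.81e-07 (adjusted p = 0.202 with an estimated correlation). The haemoglobin genes hbbe2 (-1.70) and hbaa1 (-1.39) fell, and hbae3 (-0.94) did not pass (limma adjusted p = 0.056). The other member that fell was tfa, which also stands in the list of hepatocyte markers and plasma proteins. Of 27 leukocyte genes 3 fell and 1 rose (7 lower and 2 higher when adjusted over the list alone), with a median of -0.27 and a camera adjusted p of 0.00215 (adjusted p = 0.202 with an estimated correlation). Lysozyme, lyz (-1.71), the neutrophil protease npsn (-1.58, other probes up to -0.92) and the carboxypeptidase cpa5 (-1.35) were lower, and the macrophage scavenger receptor marco (+0.86) was higher. The islet list had 5 of 21 genes lower (7 lower and 0 higher when adjusted over the list alone), with a median of -0.36 and a camera adjusted p of 0.000253 (adjusted p = 0.202 with an estimated correlation). Among these were the somatostatin genes sst2 (-2.58) and sst1.1 (-1.35), scg3 (-1.12) and neurod, which is also a neuronal gene. Intestinal genes had a median of -0.23, with 3 of 19 lower (5 lower and 0 higher when adjusted over the list alone). They were vil1 (-2.25, of uncertain size with 3 of the 4 TCS arrays well above background, and with another probe at -0.24), cldn15la (-1.85) and the apolipoprotein gene zgc:112992 (now apoa4a, -2.95), whereas fabp2 (-2.07) did not pass. The camera adjusted p of 0.0225 (adjusted p = 0.271 with an estimated correlation) became 0.0568 without TCS 2 and 0.133 with slide as a block, and ran from 0.00683 to 0.271 over the 27 alternatives. Medians within batches were -0.86 to -0.50 for red blood cells, -0.52 to -0.08 for leukocytes, -0.47 to -0.11 for the islet and -0.36 to -0.09 for the intestine. Their means of -0.77, -0.40, -0.57 and -0.51 became -0.69, -0.37, -0.53 and -0.55 with scan day as a block. With slide as a block they became -0.71, -0.36, -0.42 and -0.48. The calls of hbbe2, hbaa1, lyz, npsn, cpa5, marco, sst1.1, scg3, cldn15la and zgc:112992 were lost with scan day as a block (adjusted p = 0.0551 to 0.11). Hbaa1, lyz, npsn, marco and zgc:112992 each passed in 1 of the 8 fits that left out an array. Sst2 passed in 3 of these 8 fits and lost the call with slide row as a block (limma adjusted p = 0.0506).

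The lists of cholesterol synthesis, fatty acid oxidation, gluconeogenesis with amino acid breakdown, and foreign compound metabolism had medians between -0.48 and -0.24. Cholesterol synthesis genes had a median of -0.48 and a camera adjusted p of 0.000826 (adjusted p = 0.202 with an estimated correlation). In limma 0 of 25 passed over all features, and 0 when adjusted over the list alone (8 lower and 0 higher at an unadjusted p under 0.05). Acat2 (-0.80), mvk (-0.83), sc5d (-0.62) and hmgcs1 (-0.58) had limma adjusted p from 0.0658 to 0.13. In fatty acid oxidation 1 of 32 genes fell (4 lower and 0 higher when adjusted over the list alone), with a median of -0.28 and a camera adjusted p of 0.00034 (adjusted p = 0.251 with an estimated correlation). It was the fatty acid binding protein gene fabp1b.1 (-3.03, other probes up to -0.70), at -3.63 without TCS 1 and -2.42 without TCS 3 (adjusted p = 0.0783), while acsl4a (-1.14), acadm (-0.99) and etfa (-0.82) did not pass. Of 26 genes of gluconeogenesis and amino acid breakdown 3 fell (6 lower and 1 higher when adjusted over the list alone), with a median of -0.31. These were the glucose-6-phosphatase gene g6pca.2 (-1.80), hpda (-1.44) and mat1a (-1.34), and fbp1b (-1.42) did not pass. The camera adjusted p of 0.00403 (adjusted p = 0.202 with an estimated correlation) became 0.0742 with slide as a block, and ran from 0.000841 to 0.202 over the 27 alternatives. Xenobiotic enzymes and transporters had a median of -0.24, with 2 of 28 lower (3 lower and 0 higher when adjusted over the list alone) and a camera adjusted p of 0.00548 (adjusted p = 0.336 with an estimated correlation). The carboxylesterase gene ces2 (-3.00, or -2.39 with adjusted p = 0.0529 without TCS 3) and the efflux transporter abcc2 (-1.67) fell, and the glucuronosyltransferase genes ugt2a1 (-1.07) and ugt1ab (+0.68) did not pass (limma adjusted p = 0.0615 and 0.135). Medians within batches were -0.56 to -0.32 for cholesterol, -0.46 to -0.18 for fatty acids, -0.39 to -0.05 for gluconeogenesis and -0.31 to -0.12 for xenobiotics. The means of -0.33, -0.36, -0.39 and -0.32 became -0.34, -0.34, -0.38 and -0.30 with scan day as a block. With slide as a block they became -0.30, -0.40, -0.38 and -0.30. The calls of fabp1b.1, g6pca.2, mat1a and ces2 were lost with scan day as a block (adjusted p = 0.0917 to 0.126). Fabp1b.1, mat1a, ces2 and abcc2 each passed in 1 of the 8 fits that left out an array. Abcc2 lost the call with slide row as a block (limma adjusted p = 0.0764).

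Clock genes, listed because sampling time and light act on them, had a median of -0.29 with 5 of 32 lower (11 lower and 0 higher when adjusted over the list alone) and a camera adjusted p of 0.000332 (adjusted p = 0.202 with an estimated correlation). The transcription factor gene nfil3-6 (-2.75, of uncertain size, as 3 of the 4 TCS arrays were well above background), per1b (-2.496), cry1a (-1.42) and nr1d2b (-1.25, with another probe at -0.53) were among those that fell. Of 28 retinoid genes 6 fell and 1 rose (7 lower and 2 higher when adjusted over the list alone), with a median of -0.17. The retinol binding protein rbp2a, the plasma retinol carrier rbp4 (-1.18) and crabp1a (-0.96) were lower and meis3 (+1.24) was higher, with another meis3 probe at -0.27. The camera adjusted p of 0.0119 (adjusted p = 0.443 with an estimated correlation) became 0.0628 without DMSO 2, 0.112 with scan day as a block and 0.161 with slide as a block. Over the 27 alternatives it ran from 0.000841 to 0.443. Cartilage and matrix genes had a median of -0.13, with 6 of 40 lower (8 lower and 0 higher when adjusted over the list alone). The collagen genes col10a1 (now col10a1a, -1.73), col9a2 (-1.06), zgc:194937 (now col9a1a, -0.98) and col2a1a (-0.80) fell. Their list's camera adjusted p of 0.00334 (adjusted p = 0.202 with an estimated correlation) became 0.0773 with slide as a block, and ran from 4.44e-05 to 0.202 over the alternatives. Medians within batches were -0.47 to -0.17 for the clock, -0.27 to -0.03 for retinoid genes and -0.24 to +0.03 for cartilage, the last below 0 in 5 of the 6. The means of -0.37, -0.30 and -0.20 became -0.39, -0.21 and -0.19 with scan day as a block and -0.24, -0.21 and -0.17 with slide as a block. The calls of cry1a, rbp4, crabp1a, meis3, col9a2, zgc:194937 and col2a1a were lost with scan day as a block (adjusted p = 0.0544 to 0.0877). Col2a1a passed in 1 of the 8 fits that left out an array.

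The Nrf2, thyroid, hatching gland, reference and endothelial lists passed camera with adjusted p between 0.0225 and 0.0448, and each lost the call with an estimated correlation (adjusted p = 0.251 to 0.577). In the list of Nrf2 targets and antioxidant genes (23 tested, median -0.30; 8 lower and 3 higher when adjusted over the list alone), heme oxygenase hmox1a fell by 2.18 ± 0.43 and the autophagy adaptor sqstm1 rose by 1.33 ± 0.23. Sod2 (-0.94) and fosl1a (-0.98, with another probe at +0.38) did not pass. The camera adjusted p of 0.0225 (adjusted p = 0.577 with an estimated correlation) became 0.0936 without DMSO 2, 0.113 without TCS 2, 0.224 with scan day as a block and 0.221 with slide as a block (range over the alternatives 0.00191 to 0.577). Thyroid genes had a median of -0.14, with 2 of 22 lower (3 lower and 0 higher when adjusted over the list alone). They were thyrotropin-releasing hormone, trh (-1.13), and the deiodinase dio2 (-0.88), while slc5a5 (-0.98) and tshr (-0.98, well above background on 3 DMSO arrays and 1 TCS array) did not pass. Their camera adjusted p of 0.0446 (adjusted p = 0.251 with an estimated correlation) became 0.0635 without DMSO 4, 0.162 without DMSO 3, 0.24 without TCS 1 and 0.428 with slide as a block (range 0.0208 to 0.428). Medians within batches were -0.33 to +0.14 for Nrf2 and -0.34 to +0.04 for thyroid genes, each below 0 in 4 of the 6, and the means of -0.28 and -0.20 became -0.16 and -0.25 with scan day as a block and -0.19 and -0.10 with slide as a block. The calls of hmox1a, sqstm1, trh and dio2 were lost with scan day as a block (adjusted p = 0.0538 to 0.0649).

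Hatching gland genes (16 tested) had a median of -0.31 and common reference genes (19 tested) a median of -0.17. In both lists 0 members passed in limma over all features and 0 when adjusted over the list alone (4 and 5 lower, 1 and 0 higher, at an unadjusted p under 0.05). Among hatching genes bfb (-1.49), he2 (now he1.3, -1.46), zgc:153063 (now catip, -0.42) and tmprss13a (+0.72) had limma adjusted p from 0.0845 to 0.254. Among reference genes eif1b (-0.58), lsm12b (-0.64), sdha (-0.59) and oaz1b (-0.50) had limma adjusted p from 0.0814 to 0.205. For hatching genes the camera adjusted p of 0.0439 (adjusted p = 0.498 with an estimated correlation) became 0.0523 without DMSO 4, 0.0789 without DMSO 3, 0.0821 without DMSO 2, 0.0915 without TCS 3 and 0.154 without TCS 2. It was 0.133 with scan day and 0.238 with slide as a block (range over the alternatives 0.00718 to 0.498). For reference genes 0.04 (adjusted p = 0.458 with an estimated correlation) became 0.0628 without DMSO 2, 0.0634 without TCS 4, 0.0696 without DMSO 4 and 0.193 without TCS 3. It was 0.0688 with scan day and 0.0852 with slide row as a block (range 0.00369 to 0.458). Endothelial genes were the list with a shift upwards, with a median of +0.23 and 2 of 35 higher (0 lower and 2 higher when adjusted over the list alone). The receptor gene notch1b rose by 1.09 ± 0.20 and the scavenger receptor stab2 by 0.77 ± 0.17, while mrc1a (+0.63) and cdh5 (+0.48) did not pass. The camera adjusted p of 0.0448 (adjusted p = 0.271 with an estimated correlation) became 0.0628 without DMSO 2, 0.0675 without TCS 1, 0.0812 without TCS 4, 0.123 without TCS 3 and 0.233 without DMSO 1. It was 0.173 with slide row as a block (range 0.00906 to 0.271). Medians within batches were -0.40 to -0.12 for the hatching gland, -0.43 to -0.07 for reference and +0.11 to +0.40 for endothelial genes. The means of -0.40, -0.20 and +0.22 became -0.33, -0.18 and +0.17 with scan day as a block and -0.35, -0.30 and +0.28 with slide as a block. The calls of notch1b and stab2 were lost with scan day as a block (adjusted p = 0.0778 to 0.127). Stab2 passed in 0 of the 8 fits that left out an array.

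The stress and signalling lists below did not pass camera, unlike the Nrf2, retinoid and thyroid lists above, although single members changed. Of 31 integrated stress response genes 3 rose (0 lower and 3 higher when adjusted over the list alone), among them atf3 and the pseudokinase gene trib3 (+1.06), with a median of +0.11 (camera adjusted p = 0.336, or adjusted p = 0.716 with an estimated correlation). In the aryl hydrocarbon receptor list cyp1b1 was the 1 of 13 that rose (1 lower and 1 higher when adjusted over the list alone), and the median was +0.07 (adjusted p = 0.901, or adjusted p = 0.934 with an estimated correlation). Hypoxia targets had 2 of 29 higher (3 lower and 2 higher when adjusted over the list alone), igfbp1a and adma (+0.99), and a median of -0.11 (adjusted p = 0.358, or adjusted p = 0.726 with an estimated correlation). Of 26 glucocorticoid response genes 3 fell (7 lower and 1 higher when adjusted over the list alone), among them the co-chaperone fkbp5 (-3.00, limma adjusted p = 0.00158) and the clock gene per1b. Their median was +0.05 and their mean -0.20 (camera adjusted p = 0.192, downwards, or adjusted p = 0.299 with an estimated correlation). In the inflammation list 3 of 31 fell and 1 rose (4 lower and 4 higher when adjusted over the list alone), with lect2l (-2.76) and the chemokine gene si:dkey-25o1.6 (now ccl34b.1, -1.29) lower and mmp9 higher. Its median was +0.11 and its mean -0.07 (adjusted p = 0.8288, downwards, or adjusted p = 0.934 with an estimated correlation). The call of adma was lost with scan day as a block (adjusted p = 0.0598). Trib3 passed in 1 of the 8 fits that left out an array and lost the call with slide row as a block (limma adjusted p = 0.0648).

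Of 26 heat shock genes 1 rose (3 lower and 1 higher when adjusted over the list alone), the collagen chaperone serpinh1b (+1.37). Their median was -0.08, their mean +0.01 and the test pointed downwards (adjusted p = 0.533, or adjusted p = 0.804 with an estimated correlation). Among 25 chaperones of the endoplasmic reticulum 1 fell (1 lower and 0 higher when adjusted over the list alone), edem1 (-1.40), with a median of +0.03 and a mean of -0.05 (adjusted p = 0.488, downwards, or adjusted p = 0.821 with an estimated correlation). For oestrogen targets 1 of 21 fell (1 lower and 0 higher when adjusted over the list alone), the orphan receptor esrrga (-1.26), with a median of +0.00 and a mean of -0.03 (adjusted p = 0.533, downwards, or adjusted p = 0.716 with an estimated correlation). In the p53, cell cycle and tail bud lists limma called 0 members over all features and 0 when adjusted over the list alone. At an unadjusted p under 0.05, 3 p53 targets were higher and 3 lower, 4 cell cycle genes were higher and 0 lower, and 2 tail bud genes were higher and 0 lower. The 26 p53 targets had a median of +0.01 and a mean of -0.03 (camera adjusted p = 0.488, downwards, or adjusted p = 0.809 with an estimated correlation). The tail bud and segmentation list, with genes of earlier stages, had a median of +0.15 over 22 genes (adjusted p = 0.379, or adjusted p = 0.577 with an estimated correlation). The 36 cell cycle genes had a median of +0.16 (adjusted p = 0.124, or adjusted p = 0.726 with an estimated correlation). This list passed upwards without TCS 3 (0.0107), without TCS 2 (0.0199) and with scan day as a block (0.00185), and its adjusted p ran from 0.00185 to 0.726 over the 27 alternatives. The call of esrrga was lost with scan day as a block (adjusted p = 0.0755).

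The remaining tissue and metabolic lists did not pass camera. In the exocrine pancreas 2 of 17 genes fell (4 lower and 0 higher when adjusted over the list alone), trypsin, try (now prss1), by 2.34 ± 0.18 (limma adjusted p = 0.000851), and cpa5, which also stands in the leukocyte list. Their median was +0.04 and their mean -0.27 (camera adjusted p = 0.0578, downwards, or adjusted p = 0.202 with an estimated correlation). This list passed without TCS 3 (adjusted p = 0.0233), DMSO 2 (0.0264) or TCS 2 (0.0391), and with scan day (0.0372) or slide row (0.0401) as a block (range 0.0148 to 0.388). For heart muscle limma called 0 of 22 (5 lower and 1 higher at an unadjusted p under 0.05; 3 lower and 0 higher when adjusted over the list alone), with a median of -0.09. The adjusted p of 0.112 (adjusted p = 0.433 with an estimated correlation) became 0.0417 without TCS 4 (range 0.0417 to 0.433). Bile acid genes had a median of -0.25, with 1 of 15 lower (2 lower and 0 higher when adjusted over the list alone; camera adjusted p = 0.217, or adjusted p = 0.335 with an estimated correlation). It was cyp8b1 (now cyp8b1.1), an enzyme of cholic acid synthesis, which was not well above background on any TCS array and at least 2.71-fold lower (limma adjusted p = 0.0115). Of 28 ionocyte genes 2 fell (3 lower and 0 higher when adjusted over the list alone), pvalb9 (-2.79) and the cotransporter slc12a10.2 (-1.42), with a median of +0.05 and a mean of -0.18 (adjusted p = 0.312, downwards, or adjusted p = 0.577 with an estimated correlation). The calls of pvalb9 and slc12a10.2 were lost with scan day as a block (adjusted p = 0.0861 to 0.0964). Pvalb9 passed in 1 of the 8 fits that left out an array.

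Among 19 lipid synthesis genes the desaturase fads2 (-1.24) and agpat2 (-1.06) fell and 1 gene rose (3 lower and 1 higher when adjusted over the list alone). Their median was +0.13 and their mean -0.10 (adjusted p = 0.398, downwards, or adjusted p = 0.51 with an estimated correlation). In the kidney list the transporter slc4a4a (-0.84) was the 1 of 23 that fell (3 lower and 0 higher when adjusted over the list alone), with a median of -0.04 (adjusted p = 0.419, or adjusted p = 0.647 with an estimated correlation). The pigment list had 1 of 34 lower (1 lower and 1 higher when adjusted over the list alone), the melanosome gene pmelb (-1.05), with a median of -0.000283 (adjusted p = 0.336, or adjusted p = 0.541 with an estimated correlation). Of 28 yolk and lysosome genes 2 rose (1 lower and 4 higher when adjusted over the list alone), sqstm1 and the glucocerebrosidase gene gba (+0.93), with a median of +0.13. The adjusted p of 0.327 (adjusted p = 0.726 with an estimated correlation) became 0.0367 without TCS 2 (range 0.017 to 0.857). For the epidermis limma called 0 of 33 genes over all features and 0 when adjusted over the list alone (4 higher and 4 lower at an unadjusted p under 0.05). Its median was -0.01, its mean +0.03 and the test pointed downwards (adjusted p = 0.894, or adjusted p = 0.952 with an estimated correlation). The calls of agpat2, slc4a4a, pmelb and gba were lost with scan day as a block (adjusted p = 0.0805 to 0.115). Slc4a4a, pmelb and gba each passed in 1 of the 8 fits that left out an array.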

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

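The search for arrays far from the others of their group followed a rule set before the data were examined, and no test in this part was chosen after its result was seen. In each group of 4 arrays, the gap between the highest or lowest array and its nearest neighbour was divided by the range of the group and compared with Dixon's 95% critical value for 4 values. Of 278 groups, the DMSO and TCS groups of the named genes and of 2 array measures, 8 exceeded it, or 2.88%, whereas chance marks about 5%, or 1 in 20 groups. DMSO 1 and TCS 2 were the array apart in 3 of these groups each, and DMSO 4 and TCS 4 in 1 each.

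On TCS 2 the liver gene fabp10a had the lowest TCS value, with a log2 signal of -4.77 against -3.14 to -3.09 on the other TCS arrays (gap over range 0.973). The interferon-induced gene isg15 was lowest on TCS 2 as well, at -4.005 against -2.09 to -1.95 (0.934), and so was the autophagy adaptor sqstm1, at 1.22 against 1.98 to 2.09 (0.872). Trypsin, try, was lowest on TCS 4, at -3.54 against -3.18 to -3.12 (0.864). Among DMSO arrays, DMSO 1 had the lowest values of the lens crystallin crygmx (4.104 against 4.77 to 4.89; 0.852), the muscle gene myoz1b (3.76 against 4.19 to 4.26; 0.850) and the sterol synthesis gene sc5d (-1.98 against -1.475 to -1.42; 0.903). The lens gene lgsn was highest on DMSO 4, at 1.00 against 0.49 to 0.55 (0.879). No explanation of these single arrays was tested.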

How the results depend on the processing

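Scan day and slide row as blocks, the count of like sequences once, gene symbols alone and the joint removal of TCS 2 and DMSO 2 were chosen after the data had been seen, and the other alternatives before. The 1438 features called in the full comparison kept their direction under every alternative in which they were tested, with 2 exceptions when the probes of a gene were averaged and 1 with normexp background and the 75th percentile. Where arrays are left out this follows largely from the choice of the features, since the groups did not overlap for 1436 of them. Each alternative could give a count of features higher, of features lower and of lists. Of these values, 55 lay within 1.5 times of the reported count and 32 did not. Lists kept their side of the threshold in 1128 comparisons, lost the call in 93 and gained it in 21. The named genes did so in 2664, 789 and 93, and 0 reversed.

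Features higher in TCS numbered 192 with the array median in place of the 75th percentile. Each probe on its own gave 540 higher and 1947 lower, array weights gave 476 higher, and slide as a random block 615 and 1691. Slide as a fixed block gave 0 higher and 0 lower in limma (5602 at an unadjusted p under 0.05). That fit compares the groups on slides 1 and 4 alone, so it cannot tell an effect of slide from the loss of arrays. Scan day as a block gave 63 and 260, and slide row as a block 142 and 508. Without TCS 2 and DMSO 2 there were 5 and 48. At an adjusted p under 0.01 the genes higher in TCS numbered 16 and the genes lower in TCS 151. Of the features higher in the main fit, 93 carried a gene symbol, which is a count and not a separate test. Without 1 array, from 34 (DMSO 4) to 294 (DMSO 1) features were higher and from 217 (DMSO 2) to 1242 (TCS 1) lower. A stricter threshold and a count of gene symbols alone lower the counts by construction. For the other alternatives, left-out arrays included, the cause was not tested. With an estimated correlation camera called 0 of the 25 lists, and fry, which compares no list with other genes, called 18 of them. Fry also called the exocrine pancreas, glucocorticoid response and lipid synthesis lists (fry adjusted p = 0.0156, 0.0244 and 0.0282), which camera did not call in the main setting.

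The replicate numbers were tried as a block, and the labels do not say whether they pair the arrays. Deviations from the group means correlated across features at -0.155, 0.000825, -0.278 and 0.139 for the arrays of like number. DMSO 2 correlated best with TCS 1 (0.460). These few correlations gave no clear sign of pairing and cannot exclude it. This replicate block gave 10 features higher and 77 lower and kept 24 of the 25 lists and 16 of the 102 named genes.

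Between 90.3% and 95.9% of spots were well above background, which limits what can be said of dim transcripts. Of the changed features, 29 were not well above background on any array of 1 group, so the sizes of their fitted fold changes are uncertain.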

Other observations

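The tests of the liver list and of embryo stage were chosen after their results had been seen, as were the genes and probe groups in the first paragraphs, and the tests of chance and of features without a symbol were set before. Outside the naming rule, the gene with the smallest adjusted p that rose was zgc:110286, by 3.97 ± 0.21 on the log2 scale (limma adjusted p = 0.000417), and gng13b, a G protein subunit gene, fell by 2.80 ± 0.16 (limma adjusted p = 0.000417). Both were chosen after their values were seen. For 47 genes another probe passed the threshold with a difference over 4-fold away from that of the probe that represents the gene, which itself did not pass for 46 of them and rose for shox2 (0.9988, against -1.29 for the other probe). The cartilage matrix gene matn1 had 3 of 4 probes between -6.06 and -4.72 beside its own at -0.11. The retinoschisin gene rs1a had a probe at -4.19 beside its own at 0.46, haptoglobin, hp, a probe at -3.41 beside -0.09, and the clock gene per2 had 2 of 3 probes between -2.17 and -2.11 beside 0.31. For the myelin genes, mbpa had 2 of 10 probes between -2.97 and -2.82 beside its own at 0.32, and mbpb 2 of 5 between -2.88 and -2.86 beside -0.34.

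Probes with like sequences formed families among the changed features. The largest family higher in TCS held 45 features of non-coding RNA on chromosome 11, with a median of 1.25 and a range of 1.04 to 1.49. The next held 25 predicted genes, with a median of 1.08. Counted once per family, 229 features were higher and 1059 lower.

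All 35 splits of the 8 arrays into 4 and 4 were fitted, and other splits were scored by the larger of their directions. For the 1121 features lower in TCS, 1 of 35 splits, the real one, gave as many, and the highest other gave 500. A share of 1 in 35 is the smallest that these splits allow. It argues against chance if the arrays are exchangeable, but cannot exclude it. Arrays of 1 slide were correlated, however (consensus correlation 0.317). Slide as a fixed block left 0 features lower, but that fit compares the groups on slides 1 and 4 alone and so cannot decide the matter. Nor can chance be excluded for the 317 higher, which 2 of 35 splits reached (highest other 500), or for the 25 lists, which 3 of 35 reached (highest other 29). The split with 500 set DMSO 2, DMSO 3, TCS 1 and TCS 2 against the rest and followed no slide or scan day. It matched slide row for 7 of the 8 arrays, and a fit of slide row alone called 0 features in limma (3561 at an unadjusted p under 0.05).

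Liver plasma protein genes had a median difference of -2.30. The low signal of TCS 2 and the scan day are argued against as the whole cause, because the median was -2.18 without that array and -2.08 with scan day as a block. A shift of equal size was set against 16 of 17 tissue lists, from which the liver mean differed by -2.23 to -1.24. The exact permutation p was 0.0286, the smallest possible (adjusted p = 0.0304), which argues against an equal shift. It stays open for the retina, with a difference of -1.17 (exact permutation p = 0.0571). The rule was set and parted by list after the values were seen, and the liver list had the lowest median of all lists. The p-values take no account of that choice. A shared cause that acts unequally on the tissues is not addressed. An effect of TCS on the liver may be involved and stays a hypothesis.

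In some lists of late tissues, 19 of 28 liver, 16 of 37 retina, 16 of 42 neural and 3 of 45 muscle genes fell in TCS, and camera's list calls were lost with an estimated correlation (adjusted p = 0.079 to 0.202). Members also fell in the islet (5 of 21), cartilage (6 of 40), intestine (3 of 19), red blood cell (3 of 26) and lens lists (1 of 37, median -0.32), which camera also placed lower (adjusted p = 0.202 to 0.271 with an estimated correlation), whereas it did not call the exocrine pancreas (2 of 17), ionocytes (2 of 28), pigment (1 of 34), kidney (1 of 23), heart muscle (0 of 22) or epidermis (0 of 33). Camera placed the leukocyte list (3 of 27 lower, 1 higher) and the hatching gland list (0 of 16 passing) lower as well. The endothelial list went the other way, with 2 of 35 higher and a median of +0.23. These calls were also lost with an estimated correlation (camera adjusted p = 0.202 to 0.498). A younger stage of the TCS embryos is a candidate explanation. The tail bud and segmentation list had a median of 0.15, with a camera adjusted p of 0.379, which decides neither way. The labels give no stage by morphology, so stage and an effect of TCS on these tissues cannot be told apart.

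Features without a gene symbol had a median difference of 0.22 and gene symbols of -0.03, a gap of 0.256 that ran from 0.195 to 0.329 when 1 array was left out. The gap was 0.249 within classes of brightness, 0.177 within classes of GC content and 0.195 without TCS 2, which argues against dim probes, GC content and the low signal of that array as the whole cause. With scan day as a block it was 0.216, and the difference per array had an exact permutation p of 0.0857. No biological explanation was tested.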
